A study of Mus musculus with 4 samples.

How the data were processed

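Poly(A) RNA was measured by RNA sequencing in spermatocyte suspensions of C57BL/6 mice, in 2 control libraries and 2 libraries of an Np95 (Uhrf1) knockout. Per the labels' protocols, seminiferous tubules were cut up, digested with accutase and passed through a mesh, and no sorting step is described, so the suspensions can hold other cells of the testis. The age label reads 21 dpc for each library, and the abbreviation is not spelled out there. Libraries were made with a poly(A) selection module and the NEBNext Ultra II RNA kit, which does not mark strand, and read as 50-bp pairs on an Illumina NovaSeq, per the labels' protocols. Reads from overlapping or antisense genes can therefore not be told apart. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical.

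The deposited table holds RPKM values, reads scaled by gene length and by the library's total reads, with 1 column per library and 24444 rows named by gene symbol, per the file headers. The submitters' processing notes name Bowtie2 and the mouse genome build mm9, without a version. The counting program and the gene annotation are not given in the sources used here. Multiplying low RPKM values by the gene's length shows which length the authors divided by. By whole gene span, introns included, 52.5% to 59.3% of low values per library lay within 0.05 of a whole multiple of 1 step. By exon length the share was 9.56% to 10.5%, where 10% falls there by chance. The deposited RPKM values were thus scaled by gene span, so a gene can be compared between libraries, while levels of different genes depend on their intron content. If 1 step is 1 read or read pair, the steps correspond to about 5840000 in control replicate 1, 12850000 in control replicate 2, 11150000 in knockout replicate 1 and 4830000 in knockout replicate 2. Whole reads were not recovered for the remaining values, so no count test was run.

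Sample groups were taken from the sample titles, and each column was matched to its sample by name. From the table, 27 rows with a date in place of a symbol were left out. Where a symbol repeated, the row with the highest mean RPKM was kept, which left out 29 rows and gave 24388 symbols. Genes with RPKM of 1 or more in at least 2 of the 4 libraries were tested, 9099 in all. A gene below 1 RPKM in both libraries of 1 group therefore passed only if both libraries of the other group reached 1 RPKM. Values were converted to log2(RPKM + 1) and the knockout was compared with the control by limma 3.58.1 with a mean-variance trend (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 fold change is on this scale, which understates the change of low genes, while a fold is the ratio of mean RPKM. An exact permutation test of 2 against 2 cannot go below p = 0.333, so no call rests on permutation of single genes.

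Gene lists were written from general knowledge of the testis before the data were examined, as were the main test, most of the alternatives and the rule for naming genes. Each of the 24 sets tested (the lists with 5 or more tested members and the X-linked and Y-linked genes) was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the sets. Camera with a correlation estimated from the residuals, and fry, were alternatives. The list of mitochondrially encoded transcripts had 0 members in the tested genes and the Rhox list had 2, so neither was tested as a set. Chromosomes were taken from the RefSeq gene table of GRCm38.p6 by symbol, for 9060 of the tested genes (99.6%), and no coordinate of that build is given because the authors' build was mm9. The rule names Uhrf1, then the 12 genes per direction with the largest log2 fold change among those called, separated between groups and with a group mean of at least 5 RPKM. It then names up to 4 called members per list with the smallest p, and the 2 most abundant members of each list of other cell types. Genes outside the rule are named where a count of 5 or fewer calls for it, and those were chosen after their values were seen.

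The fit was tested on simulated data with the real means and spread of the 9099 genes, 2 libraries against 2. It recovered 54 of 100 genes changed 2-fold and 4 of 100 genes changed 1.41-fold, with 1 false call among 59. Of simulated unchanged lists, 4.5% passed a p of 0.05 in camera. The simulated genes varied independently of each other, so this share does not cover lists whose genes move together. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, 3 other scalings between libraries (equal RPKM sum, equal median, quantile normalization), limma without the trend, a replicate block, each library left out, and summed rows of a repeated symbol. A minimum fold of 2, the removal of microRNA and small nucleolar RNA rows, and an adjustment of the X-linked set for gene span and expression were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.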

Results

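The data are RNA-sequencing profiles of mouse spermatocytes, the germ cells that pass through meiosis, from 2 control libraries and 2 libraries in which Np95 had been knocked out. Np95, whose gene symbol is Uhrf1, binds hemimethylated DNA and brings the maintenance methyltransferase Dnmt1 to it after replication. The study asked how maintenance DNA methylation set up before meiosis bears on meiotic prophase. The steps between low RPKM values correspond to about 5840000 and 12850000 reads or read pairs in control replicates 1 and 2, and to about 11150000 and 4830000 in knockout replicates 1 and 2, so knockout replicate 2 and control replicate 1 are the least precise for low genes. Across tested genes, Pearson's r of log2 values was 0.993 between the control libraries, 0.977 between the knockout libraries and 0.790 to 0.884 between groups. These correlations are across genes, which are not independent replicates. All group values below are mean RPKM ± SD over 2 libraries, and adjusted p-values are from limma for genes and from camera for gene lists.

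Uhrf1, on chromosome 17, was lower in both libraries labelled as knockout. Its RPKM was 3.20 ± 0.123 in the control (SD, n = 2) and 1.68 ± 0.276 in the knockout (SD, n = 2), 1.91-fold lower, with a log2 fold change of -0.65 (SE 0.10, limma adjusted p = 0.0031). The RPKM covers the whole gene and the deleted part is not named in the labels, so this value does not give the loss of the deleted part.

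Expression differed between the groups over most of the genes tested. In the knockout 3943 genes were higher and 2776 were lower, 73.8% of the 9099 tested, and 2380 were not called. A change of at least 2-fold on the log2(RPKM + 1) scale was met by 965 of the higher and 840 of the lower genes. The values of the 2 groups did not overlap for 89.9% of genes, where chance gives 33.3%. The split of the calls depended on the scaling between libraries. As deposited, 58.7% of calls were higher and the median log2 fold change of all genes was 0.14. With libraries scaled to an equal RPKM sum 5657 genes were higher and 1663 lower (77.3% higher, median 0.46), with libraries centred on an equal median 3045 and 3538 (46.3%, median -0.05), and with quantile normalization 3157 and 3042 (50.9%, median 0.01). Medians of gene lists are therefore given after subtraction of the 0.14 median of all genes. Log2 fold changes also fell with expression level, with a Spearman correlation of -0.31 with mean expression across genes. Among genes at 5 RPKM or more the median log2 fold change was -0.22. The list tests were not adjusted for expression level, so lists of abundant genes can lie lower for this reason.

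Among the 12 genes named for the largest falls were several known from the testis. Hspb9, a small heat shock protein of the testis, fell from 987 ± 226 to 89.8 ± 39.0 RPKM, a log2 fold change of -3.49. Pgk2, the testis phosphoglycerate kinase, was 6.75-fold lower, and Pou5f2, a POU transcription factor of spermatocytes, was 6.21-fold lower. Cetn1, the testis centrin, fell from 577 ± 21.7 to 102 ± 39.6 RPKM, and Pgam2, a phosphoglycerate mutase of muscle and testis, from 301 ± 4.82 to 53.5 ± 19.12. Dbil5, a testis relative of the diazepam-binding inhibitor, was 6.64-fold lower, Fam98c 6.83-fold and Mesp1 6.03-fold. Mesp1 had 82.0 ± 1.47 RPKM in the control, against 18.2 and 9.02 in knockout replicates 1 and 2. The genes 1700020D05Rik and 4933427E11Rik were 5.88-fold and 5.96-fold lower, Tex40 was 5.88-fold lower, and the microRNA row Mir7666 was 6.88-fold lower. Mir7666 had 35.2 ± 6.58 RPKM in the control, against 7.69 and 2.55 in knockout replicates 1 and 2. The adjusted p of these 12 genes ran from 0.0014 to 0.0038.

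Of the 12 genes named for the largest rises, 4 were on the X chromosome, and the adjusted p of the 12 ran from 0.0014 to 0.028. Ubqln2, an X-linked ubiquitin-binding shuttle of the proteasome, rose from 4.26 ± 0.874 to 26.7 ± 4.75 RPKM, 6.28-fold. The X-linked genes Tex13, expressed in germ cells, and Otud6a, a deubiquitinase, rose 5.86-fold and 6.91-fold. Sox9, the transcription factor of Sertoli cells, rose from 1.39 ± 0.340 to 11.6 ± 4.56 RPKM, 8.38-fold. Sox4, a related transcription factor, rose 6.91-fold, Atp1b2, a subunit of the sodium pump, 6.00-fold, and Scd2, a fatty acid desaturase, 5.57-fold. The remaining 5 of the 12 were microRNA rows, whose short spans share reads with host or neighbouring genes. Among them Mir5113 rose from 0.463 ± 0.0908 to 5.95 ± 1.20 RPKM and Mir5114 4.96-fold. Mir3113, on the X chromosome, was listed at 0 in control replicate 1 and at 0.390 in control replicate 2, against 3.47 and 8.84 RPKM in the knockout libraries. Mir1902 had 2.19 ± 2.38 RPKM in the control and 14.3 ± 2.75 in the knockout, and Mir8101 had 3.22 ± 3.49 and 15.7 ± 5.86. The call of Mir8101 ended without knockout replicate 1 (adjusted p = 0.065), without knockout replicate 2 (0.14) and without the filter (0.084), and that of Mir1902 ended without knockout replicate 2 (0.068).

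**Figure D1:**
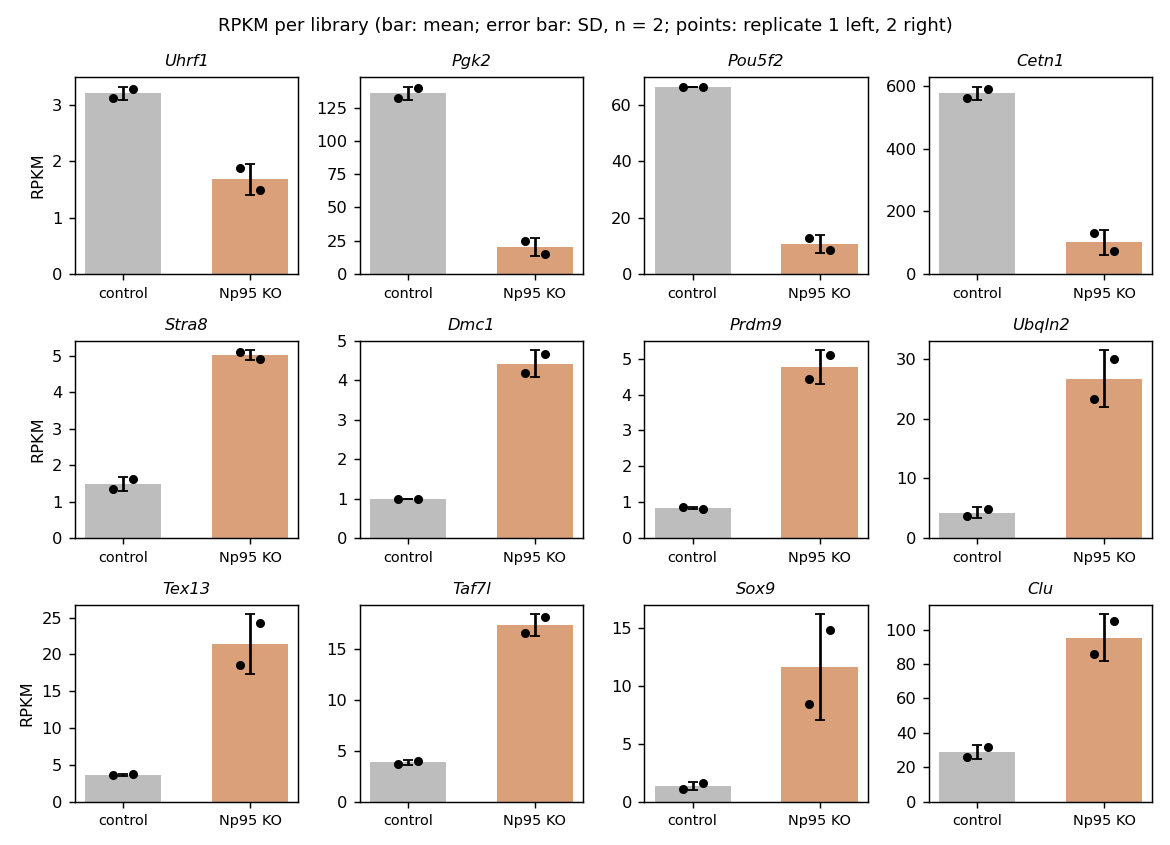
RPKM (vertical axes, each from 0) of 12 genes in the control (grey) and Np95 knockout (orange) libraries, with bars for the mean, error bars for the SD (n = 2) and points for the libraries, replicate 1 on the left. Uhrf1, Pgk2, Pou5f2 and Cetn1 are lower and the other genes higher in both knockout libraries, with Pgk2 6.75-fold lower and Ubqln2 6.28-fold higher.

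Genes of pachytene and later spermatocytes fell together, while genes of meiotic entry rose. Of 19 pachytene genes tested, 17 fell and 2 rose, with a list median of -1.15 and a median RPKM ratio of 0.429 (camera adjusted p = 6.30e-05, and adjusted p = 0.469 with an estimated correlation). Besides Pgk2 and Pou5f2, the sperm surface proteins Adam2 and Adam3 were 3.07-fold and 4.43-fold lower. The genes that rose were Sycp1, which is also transcribed from early prophase, and Mybl1, a transcription factor of meiotic cells. Of 30 spermatid genes listed, 9 passed the filter, of which 6 fell and 3 were not called (median -0.75, camera adjusted p = 0.016, and adjusted p = 0.469 with an estimated correlation). Most of this list, with Tnp1, Prm1 and Prm2 among them, was below the filter. Without the filter 13 of 29 were lower and 0 higher, with a median log2 fold change of -0.11 before subtraction. Dnajb3 was 3.99-fold lower, the acrosin gene Acr 2.96-fold, the kinase gene Tssk1 2.86-fold and Crem, a transcription factor of spermatids, 2.03-fold. In the meiotic entry list 8 of 11 genes rose, 1 fell and 2 were not called (median 0.97, camera adjusted p = 0.023, and adjusted p = 0.469 with an estimated correlation). Stra8, the retinoic acid target at meiotic entry, rose from 1.49 ± 0.194 to 5.02 ± 0.137 RPKM, 3.36-fold. Prdm9, which marks recombination hotspots, rose 5.68-fold, the recombinase gene Dmc1 4.47-fold, and the X-linked cyclin gene Ccnb3 8.06-fold. Prdm9, Dmc1 and Ccnb3 were below 1 RPKM in both control libraries, so they passed the filter through the knockout libraries only. The gene that fell was Spo11, the nuclease of meiotic breaks, which is also transcribed later in prophase. Of 21 spermatogonial genes listed, 6 passed the filter, of which 4 rose and 2 fell (median 0.55 after subtraction, mean 0.13 before it, camera adjusted p = 0.61). Without the filter 14 of 21 were higher and 2 lower (camera adjusted p = 0.049). Sohlh1 rose 3.35-fold and Dmrt1 4.25-fold, both transcription factors of spermatogonia, while Dmrtb1 was 4.05-fold and Id4 1.75-fold lower. Dmrt1 was below 1 RPKM in both control libraries. The call of the meiotic entry list ended with an equal RPKM sum (adjusted p = 0.055), and that of Id4 ended with quantile normalization. In the same knockout libraries all 15 Sertoli cell genes and 14 of 17 dissociation and stress genes were higher, as given below.

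Genes of the chromosome axis and of recombination moved both ways. In the list of the synaptonemal complex, axis and meiotic cohesin, 7 of 14 genes rose, 2 fell and 5 were not called (median 0.12, camera adjusted p = 0.24). The cohesin genes Rec8, Rad21l and Smc1b rose 3.27-fold, 4.52-fold and 2.09-fold, and 4930447C04Rik, which codes for a synaptonemal complex protein, rose 2.73-fold. Rad21l was below 1 RPKM in both control libraries. The genes that fell were Syce1 and Syce3, of the central element of the complex. For break formation and recombination, 15 of 23 genes rose, 6 fell and 2 were not called (median 0.29, camera adjusted p = 0.18). Tex15 rose from 6.02 ± 0.202 to 28.9 ± 0.0121 RPKM, 4.79-fold, and Rad51ap2 3.74-fold, both with roles in meiotic recombination. These libraries measure transcript levels and hold no measurement of pairing or of breaks. All 15 Sertoli cell genes and 14 of 17 dissociation and stress genes were higher in the same knockout libraries.

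The piRNA pathway, which silences transposons in germ cells through small RNAs, was lower. Of 22 genes tested, 13 fell, 3 rose and 6 were not called, and 14 fell when p was adjusted over the list alone (median -0.52, camera adjusted p = 0.0066, and adjusted p = 0.469 with an estimated correlation). Pld6, an enzyme of piRNA processing, fell from 75.8 ± 6.19 to 22.9 ± 4.49 RPKM, 3.31-fold. Mael and Gtsf1 were 2.46-fold and 2.68-fold lower. The genes that rose were Fkbp6, 1.81-fold, Mybl1 and Mov10l1. The list shares Piwil1, Tdrd6 and Mybl1 with the pachytene list. Its call ended when only genes at 5 RPKM or more were tested (adjusted p = 0.13), and with an equal RPKM sum 7 of its genes were higher and 7 lower. It had 10 genes lower and 1 higher without control replicate 1, and 9 and 1 without control replicate 2. All 15 Sertoli cell genes were higher in the same knockout libraries, with a median RPKM ratio of 3.29.

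Sex-linked genes were higher as a class. Of 265 X-linked genes tested, 251 rose (94.7%), 4 fell and 10 were not called, and 253 rose when p was adjusted over the list alone. Genes below 1 RPKM in both control libraries passed the filter only through the knockout libraries. Without the filter 553 of 923 X-linked genes were higher and 22 lower. Their median log2 fold change was then 0.20 before subtraction, against 0.04 for all genes. With the filter, 41.7% of 8788 autosomal genes rose and 31.4% fell. Before subtraction of the median of all genes, the median log2 fold change was 1.06 on the X chromosome, with a median RPKM ratio of 3.35. It was 0.11 on the autosomes, where single chromosomes ran from -0.00 on chromosome 17 to 0.22 on chromosome 18. After subtraction the X-linked median was 0.92 (camera adjusted p of the X-linked genes = 5.15e-20, and adjusted p = 0.469 with an estimated correlation). All 7 Y-linked genes tested rose, with a median RPKM ratio of 3.77 (camera adjusted p = 0.0066, and adjusted p = 0.469 with an estimated correlation). They were Ddx3y, Eif2s3y, Uba1y, Gm3376 and the rows Gm10256, Gm10352 and Gm4064, which held identical values and are not separate measurements. Without the filter 17 of 19 Y-linked genes were higher and 0 lower. The X-linked genes that fell were Tsga8 and H2afb3, which are expressed in spermatids, Gm6568 and Gm6787. The list of sex-linked genes of early germ cells rose in 12 of 12 members (median 1.06 after subtraction, camera adjusted p = 2.2e-04, and adjusted p = 0.469 with an estimated correlation), and without the filter in 20 of 20. This list holds X-linked and Y-linked genes already counted above, among them Ddx3y, Eif2s3y and Uba1y. It was not restricted to genes that somatic testis cells do not express. Its members Tktl1, Tex16 and Scml2 were below 1 RPKM in both control libraries. Taf7l, a germ cell relative of a general transcription factor subunit, rose from 3.85 ± 0.232 to 17.3 ± 1.07 RPKM, 4.49-fold, Tktl1 5.31-fold, Tex16 4.90-fold and Scml2, a Polycomb protein of the germ line, 4.17-fold. Both Rhox genes tested rose, Rhox8 3.11-fold and Rhox13 3.76-fold. The X-linked and Y-linked sets kept their direction and their side of the threshold under each scaling. The Sertoli cell genes, of which Gata1 is X-linked, rose in the same libraries.

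**Figure D2:**
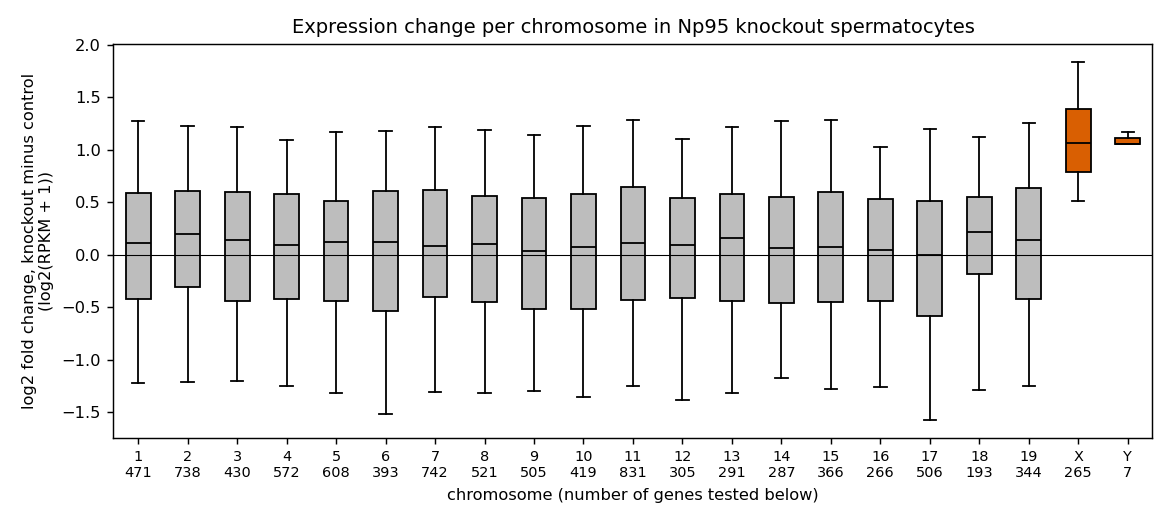
Log2 fold change of the tested genes on each chromosome, knockout minus control on the log2(RPKM + 1) scale, with boxes for the quartiles, a line for the median and whiskers for the 5th and 95th percentiles, and the number of genes under each name. The median is 1.06 for the X and 1.05 for the Y chromosome, and lies between -0.00 and 0.22 for the autosomes.

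Autosomal retrogenes, which stand in for X-linked parent genes when the X chromosome is silent, were lower in 5 of 9 cases and not called in 4 (median -0.52, camera adjusted p = 0.013, and adjusted p = 0.469 with an estimated correlation). Pgk2 and Cetn1 head this list too, the ribosomal protein gene Rpl10l fell from 393 ± 9.10 to 178 ± 20.2 RPKM, 2.21-fold, and Pdha2, of pyruvate dehydrogenase, was 1.99-fold lower. With quantile normalization the direction of the list turned (adjusted p = 0.89) and the calls of Rpl10l and Pdha2 ended, with an equal RPKM sum 4 of the genes were lower and 2 higher, and at 5 RPKM or more the call of the list ended (adjusted p = 0.13). Of 16 genes of sex chromosome silencing and DNA damage signalling 9 rose, 0 fell and 7 were not called (median 0.15, camera adjusted p = 0.11), while 5 rose and 2 fell with median centring, 8 rose and 2 fell with quantile normalization, and 14 rose and 0 fell with an equal RPKM sum. Without control replicate 1, 5 of them rose and 1 fell. The kinase genes Atm and Chek1 rose 5.32-fold and 2.91-fold, and Brca1 3.48-fold. Atm, Chek1 and Brca1 were below 1 RPKM in both control libraries, so they passed the filter through the knockout libraries only. Without the filter 10 of 18 genes of this list were higher and 0 lower. The same knockout libraries had higher values of all 15 Sertoli cell genes and of 14 of 17 dissociation and stress genes.

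Genes of the DNA methylation machinery rose in 6 of 9 cases, 1 fell and 2 were not called (median 0.38, camera adjusted p = 0.20). Dnmt1, the maintenance methyltransferase, rose from 2.04 ± 0.0453 to 3.47 ± 0.240 RPKM, 1.70-fold. Hells, a remodeller that helps methylate heterochromatin, rose 3.60-fold, the DNA ligase gene Lig1 2.81-fold and the glycosylase gene Mbd4 2.46-fold, and Mbd3, of the NuRD complex, fell. Mbd4 was below 1 RPKM in both control libraries. Germline genes that promoter methylation silences in somatic cells moved both ways, with 8 of 24 higher, 12 lower and 4 not called (median -0.26, camera adjusted p = 0.24). The balance depended on the scaling, with 12 of 23 higher and 4 lower with an equal RPKM sum and 9 of 24 higher and 8 lower with quantile normalization. Without control replicate 1, and again without control replicate 2, 6 were higher and 6 lower. Dazl, an RNA-binding protein of germ cells, rose 2.65-fold, while Mael was 2.46-fold and Tuba3a 3.04-fold lower. Tuba3a and Tuba3b are near-identical and share reads. Of 15 imprinted genes 11 rose, 3 fell and 1 was not called (median 0.63, camera adjusted p = 0.076). Igf2, a paternally expressed growth factor, rose from 0.452 ± 0.0747 to 3.07 ± 0.0940 RPKM, 6.80-fold, Gnas 2.96-fold, Cdkn1c 2.46-fold and Ndn 2.17-fold. Igf2 was below 1 RPKM in both control libraries, so it passed the filter through the knockout libraries only. The imprinted genes that fell were Mirg, Mcts2 and Zrsr1. In the heterochromatin list 10 of 19 genes rose, 3 fell and 6 were not called (median 0.25, camera adjusted p = 0.24). The X-linked histone methyltransferase gene Suv39h1 rose 4.82-fold and Morc2a 1.90-fold, while the histone demethylase gene Kdm4d was 2.54-fold lower, and Morc2b and Kdm3a also fell. Somatic cell markers rose in the same libraries, so these values are of a mixed suspension.

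Markers of somatic testis cells were higher in the knockout. All 15 Sertoli cell genes rose (median 1.35, camera adjusted p = 2.2e-04, and adjusted p = 0.469 with an estimated correlation), and without the filter 18 of 19 did. Clu rose from 28.9 ± 4.25 to 95.3 ± 13.5 RPKM, 3.29-fold, Aard from 53.02 ± 4.62 to 152 ± 19.5, 2.88-fold, Wt1 4.33-fold, Cldn11, of Sertoli cell tight junctions, 4.55-fold, Vim 3.72-fold and Ctsl 2.84-fold. Wt1 was below 1 RPKM in both control libraries. Of 14 peritubular, stromal and endothelial genes listed, 6 passed the filter and all 6 rose, among them the collagen genes Col1a1 5.82-fold, Col1a2 4.18-fold and Col3a1 3.76-fold and the receptor gene Pdgfra 4.96-fold (median 0.94, camera adjusted p = 0.031, and adjusted p = 0.469 with an estimated correlation). Pdgfra was below 1 RPKM in both control libraries. Without the filter 10 of 14 of these genes were higher and 0 lower. Of 9 Leydig cell genes 7 rose, 1 fell and 1 was not called (median 0.81, camera adjusted p = 0.087). The hormone gene Insl3 rose 3.13-fold, Nr5a1 3.90-fold, the steroid enzyme gene Hsd3b1 2.85-fold, Scarb1 3.08-fold and Star 1.96-fold, and Fdx1 fell. Of 14 leukocyte genes listed, 5 passed the filter and all 5 rose, C1qc 3.04-fold, C1qb 2.35-fold, C1qa 2.48-fold, Cd68 3.04-fold and Lyz2 1.84-fold (median 0.72, camera adjusted p = 0.064). C1qb and Cd68, and Scarb1 of the Leydig list, were below 1 RPKM in both control libraries. Without the filter 9 of 14 leukocyte genes were higher and 0 lower. None of 6 haemoglobin rows was called (median -0.25, camera adjusted p = 0.68, 0 also adjusted over the list alone, and 0 by an unadjusted limma p under 0.05). Hbb-b1 had 38.2 ± 3.70 RPKM in the control and 37.6 ± 18.8 in the knockout, and Hbb-bs 37.9 ± 3.68 and 37.4 ± 18.6. Hba-a1 had 5.32 ± 0.0684 and 6.59 ± 3.81 RPKM, and Hba-a2 5.31 ± 0.0682 and 6.58 ± 3.80, rows that share reads. Single knockout libraries decided these rows, since without knockout replicate 1 Hba-a1 and Hbb-b1 were called higher (log2 fold change 0.70 and 0.41) and without knockout replicate 2 lower (-0.37 and -0.62). The Leydig list passed without control replicate 1 (adjusted p = 0.042) and the leukocyte list without control replicate 2 (0.035) or knockout replicate 2 (0.049), and the peritubular call ended with an equal RPKM sum (0.10). The call of Star ended without control replicate 2 (0.14) or knockout replicate 2 (0.12), and that of C1qa without control replicate 1 (0.11) or knockout replicate 1 (0.090). Both also ended with median centring, with quantile normalization and without the filter.

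Stress and signalling lists were also higher. Of 17 genes of dissociation and stress response 14 rose, 2 fell and 1 was not called (median 1.24, camera adjusted p = 0.026, and adjusted p = 0.469 with an estimated correlation). The immediate early gene Egr1 rose 6.65-fold, Btg2 5.83-fold, and the heat shock genes Hspb1 and Hspa1b 4.67-fold and 6.32-fold, and Ddit3 and Dnajb1 fell. Of 13 p53 targets and apoptosis genes 11 rose, 1 fell and 1 was not called (median 0.80, camera adjusted p = 0.026, and adjusted p = 0.469 with an estimated correlation). The cell death genes Pmaip1 and Bax rose 2.84-fold and 2.15-fold, Ccng1 4.10-fold and Sesn2 3.45-fold, and Bak1 fell. Of 22 interferon response genes listed, 5 passed the filter and all 5 rose, among them Oasl2 by a log2 fold change of 1.17, Irf9 4.06-fold, Irf7 4.05-fold and Bst2 3.58-fold (median RPKM ratio 4.05, camera adjusted p = 0.026, and adjusted p = 0.469 with an estimated correlation). Oasl2, Irf7 and Bst2, and Btg2 of the stress list, were below 1 RPKM in both control libraries, so they passed the filter through the knockout libraries only. Without the filter 14 of 21 interferon genes were higher and 1 lower, with a median log2 fold change of 0.19 before subtraction. With an equal RPKM sum the calls of these 3 lists ended (adjusted p = 0.11, 0.067 and 0.084). The call of the p53 list also ended at 5 RPKM or more (adjusted p = 0.069) and without the filter (adjusted p = 0.051). All 15 Sertoli cell genes and all 6 peritubular genes were higher in the same libraries. From knockout replicate 1 to 2 the stress, p53 and interferon lists rose along with the Sertoli list (median log2 RPKM ratio 0.45, 0.32 and 0.35, against 0.41). Adjusted over the list alone, the counts of every list but the piRNA and X-linked ones were equal to those over all genes.

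**Figure D3:**
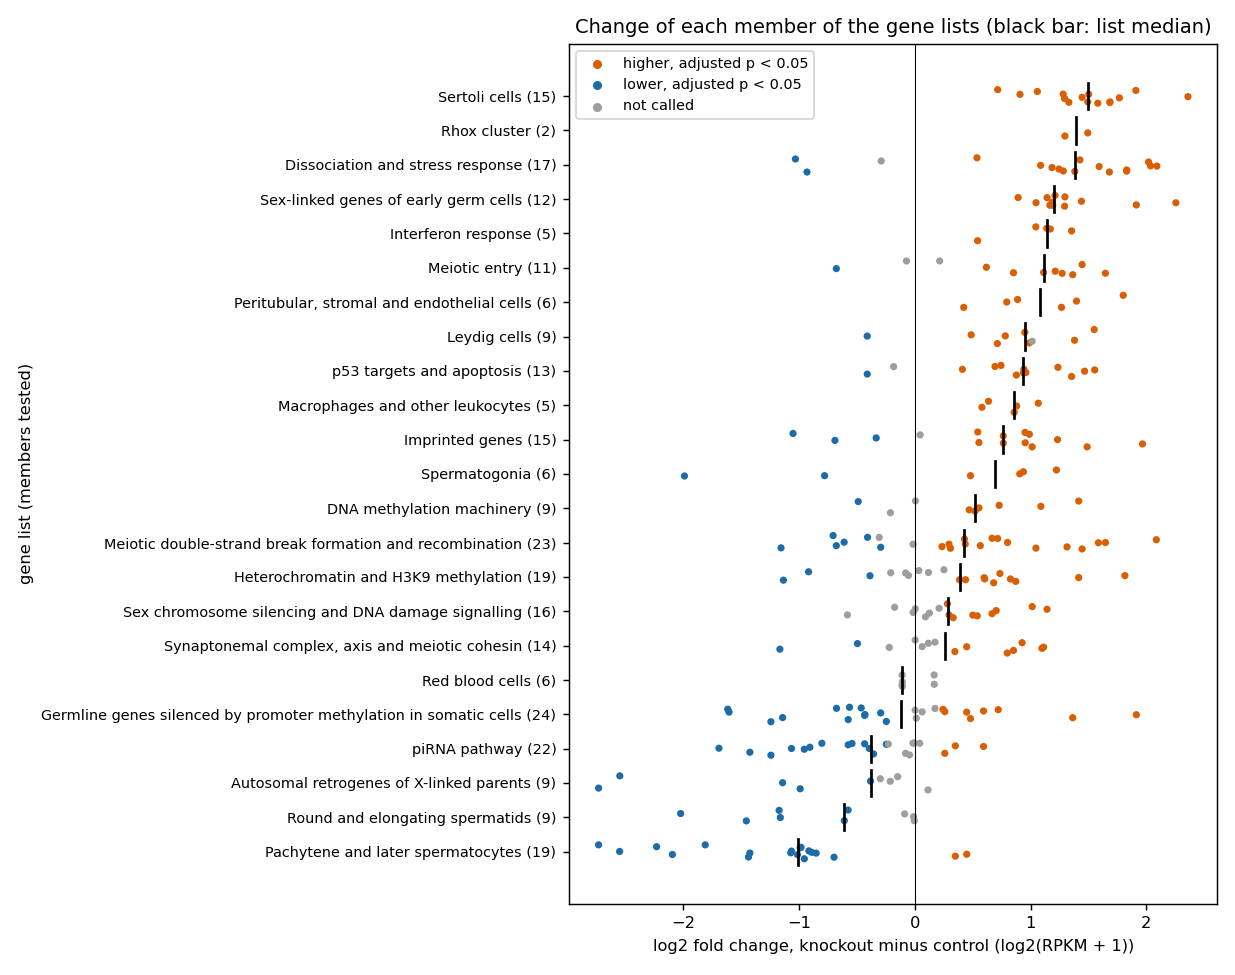
Log2 fold change of each tested member of the gene lists (knockout minus control on the log2(RPKM + 1) scale, horizontal axis), with the number tested in brackets, orange for higher, blue for lower, grey for not called and a black bar for the list median. The median of all genes is not subtracted here. All 15 Sertoli cell genes lie above 0, and 17 of 19 pachytene genes lie below 0.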

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

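The minimum fold, the removal of small RNA rows and the adjustment of the X-linked set were chosen after seeing the data, and the other alternatives before. Pseudocounts of 0.1 and 0.5, limma without the trend, summed rows and removal of small RNA rows ended or turned none of the list and chromosome calls or the calls of named genes, and moved no gene count by over 1.5 times. No alternative that left out a library turned the direction of a gene called over all libraries, while quantile normalization turned 195 of those calls. An equal RPKM sum shifts all genes of a library by nearly 1 amount (median log2 fold change from 0.14 to 0.46), so the 227 calls it turned are of genes that this shift carried across 0. The causes were not tested, except that another filter changes the genes tested. Without a filter 7370 genes were higher, of 21208 tested. The lists of DNA methylation, recombination, imprinting and sex chromosome silencing then passed (adjusted p = 0.026 each), as did spermatogonia (0.049) and leukocytes (0.039), and p53 did not (0.051). At 5 RPKM or more, with 3468 genes tested, 1080 were higher and 1629 lower, the piRNA (0.134), retrogene (0.134) and p53 (0.0694) calls ended, and the red blood cell list turned direction (0.694). The lists of DNA methylation, meiotic entry, spermatogonia, spermatids, Leydig cells and peritubular cells kept fewer than 5 members there and were not tested. The same holds for leukocytes, interferon, sex-linked genes of early germ cells and the Y-linked genes. At least 2-fold, 965 genes were higher and 840 lower.

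With an equal RPKM sum 1663 genes were lower, the calls of meiotic entry (adjusted p = 0.0552), peritubular cells (0.101), p53 (0.0669), interferon (0.0844) and stress (0.112) ended, and spermatogonia turned direction (0.950). Median centring added calls of Leydig cells (0.0374), leukocytes (0.0348) and imprinted genes (0.0342). Quantile normalization added DNA methylation (0.0435) and heterochromatin (0.0338) and turned the germline genes (0.879), red blood cells (0.666) and retrogenes (0.893). With an estimated correlation the 13 calls by camera all ended, at adjusted p = 0.469. That correlation rests on residuals of 4 libraries. By fry, which tests whether a list moves on balance 1 way and not against other genes, adjusted p was 0.0129 for DNA methylation, 0.0167 for the synaptonemal complex, 0.00204 for recombination, 0.0217 for spermatogonia and leukocytes, 0.00335 for Leydig cells, 0.0114 for imprinted genes, 0.00798 for sex chromosome silencing and heterochromatin, and 0.781 with the other direction for germline genes. The haemoglobin rows, not called over all 4 libraries, changed sign: Hbb-b1 and Hbb-bs to 0.30 with an equal RPKM sum, 0.46 with quantile normalization and 0.41 without knockout replicate 1, Hba-a1 to -0.0251 and Hba-a2 to -0.0245 with median centring and both to -0.37 without knockout replicate 2. Their whole ranges without single libraries ran from -0.62 to 0.41 for the Hbb rows and from -0.37 to 0.70 for the Hba rows.

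With 1 library left out, the lone library of its group is assumed to vary like the others. Genes higher ran from 3034 to 3949, genes lower from 2085 to 2902, and the log2 fold change of Uhrf1 from -0.76 to -0.55. Adjusted p ran from 0.0418 to 0.0732 for Leydig cells, which passed without control replicate 1 only, from 0.0353 to 0.111 for leukocytes, which passed without control replicate 2 and without knockout replicate 2 (0.0487), and from 0.0191 to 0.819 for red blood cells, which passed without knockout replicate 2 and turned direction without knockout replicate 1 (0.112). The other lists and both chromosome sets kept their direction and side of the threshold. The replicate numbers are shared between the groups in the labels, with nothing to say that they pair the samples, and the differences between replicates 1 and 2 in the 2 groups correlated at 0.11 across genes. With the replicate number as a block 3868 genes were higher and 2721 lower, and no call of a list or named gene changed. Neither depth nor the number of libraries was varied in the simulated data, where at 2 against 2 libraries 54 of 100 genes changed 2-fold were recovered and 4 of 100 changed 1.41-fold. That simulation changed few of the 9099 genes, while 73.8% were called here.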

Other observations

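The gene families and all tests in this part were chosen after the results had been seen. Families of 10 or more tested genes that share a symbol stem were compared with all other genes by camera, 98 in all, and 8 were called, all 8 lower, with a lowest adjusted p = 0.893 with an estimated correlation. Family medians are log2 fold changes after subtraction of the median of all genes under the same scaling, and those of the 8 called families were also below 0 with quantile normalization. Log2 fold changes fell with mean expression across genes (Spearman correlation -0.31). The family tests were not adjusted for this, so a family of abundant genes can look lower through its level. The same libraries had higher values of all 15 Sertoli cell genes and of 14 of 17 dissociation and stress genes. All 16 Cfap genes, named for cilia and flagella, fell (median -1.09, adjusted p = 3.05e-05), and 13 fell and 0 rose with an equal RPKM sum. Cfap206 fell from 19.5 to 5.46 RPKM and Cfap161 from 4.92 to 1.18. Of 13 Ift genes, of transport along the cilium, 11 fell and 0 rose (median -0.55, adjusted p = 0.0022), and 4 fell and 0 rose with an equal RPKM sum. Of 77 coiled-coil Ccdc genes 47 fell and 9 rose (median -0.64), and of 19 Ttc genes 16 fell and 2 rose (median -0.76). With an equal RPKM sum 36 Ccdc genes fell and 21 rose, and 11 Ttc genes fell and 3 rose.

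Of 41 Nduf genes, of respiratory complex I, 26 fell and 6 rose (median -0.55, adjusted p = 3.37e-04), and of 43 Mrpl genes, of the large subunit of the mitochondrial ribosome, 23 fell and 3 rose (median -0.45, adjusted p = 3.37e-04). With an equal RPKM sum 15 Nduf genes fell and 9 rose, and 16 Mrpl genes fell and 12 rose. Other families of mitochondrial proteins were not called, namely Mrps (6 of 25 higher and 7 lower, adjusted p = 0.42), Cox (6 of 21 higher and 11 lower, 0.23), Timm (2 of 14 higher and 5 lower, 0.58) and Tomm (3 of 11 higher and 4 lower, 0.58). Of 10 Dnajb genes, heat shock protein partners, 7 fell and 0 rose (median -0.95, adjusted p = 0.010), against 6 and 2 with an equal RPKM sum. Of 512 genes with a Rik symbol 297 fell and 113 rose, against 222 and 162 with an equal RPKM sum. The cytosolic ribosomal protein families Rps and Rpl were not called (adjusted p = 0.062 and 0.079), and their medians of -0.38 and -0.22 became 0.04 and 0.09 with quantile normalization.

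The first pattern is the rise of X-linked genes relative to autosomal genes. Gene span and expression level of whole-gene RPKM do not account for it, since the difference of medians between X-linked and autosomal genes was 0.95 before and 0.86 after both were adjusted for, and 0.80 to 0.91 over the 4 pairs of a knockout and a control library. More somatic cells alone would not raise X-linked genes of germ cells. From the list of sex-linked genes of early germ cells, X-linked genes taken as expressed in germ cells and not in somatic testis cells were used. Of these, 7 of 7 (Taf7l, Tex13, Tex16, Nxf2, Usp26, Pramel3 and Rhox13) rose, with a median log2 fold change of 1.29 and a lowest value of 0.89. Somatic cells may add to the rest of the X-linked genes. The 7 germ-cell genes were chosen from a list already seen to rise, so their rise is not a separate test. A smaller share of cells at the stage that silences the sex chromosomes, with silencing intact, cannot be told apart from a loss of silencing in the knockout: the median log2 RPKM ratio was 2.17 for these genes and 1.23 for 10 autosomal genes of meiotic entry (exact permutation p over genes = 0.0356, two-sided), but the lowest of the former, 1.72, lay below the highest of the latter, Prdm9 at 2.51, and Spo11, Rbm46 and Meioc are also transcribed later. As a hypothesis, incomplete silencing of the sex chromosomes in knockout spermatocytes stays open beside a shift of cell stages, and cells sorted by stage would separate these.

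The second pattern is the rise of somatic cell markers in the knockout, in a suspension with no sorting step in its labels. The loss of abundant transcripts would raise the other genes alike on the RPKM scale. Centring the libraries on an equal median removes such a common shift, and 15 of 15 Sertoli genes were still called higher there. A common shift alone therefore does not account for the rise of the Sertoli genes. With quantile normalization their median log2 fold change was 1.73, with 15 of 15 genes called. The log2 ratio of the RPKM sums of control over knockout was 0.42. That ratio rests on values scaled by gene span, so it does not bound the shift. A lower share of germ cells that raises the other nucleated cell types alike cannot be told apart from a larger change in some types, since the median log2 RPKM ratios of the Sertoli, Leydig, peritubular and leukocyte lists were 1.72, 1.51, 1.99 and 1.31 (permutation p over genes = 0.0516), a difference this few genes do not decide. The haemoglobin rows, whose level depends on blood left with the tubules, had a median RPKM ratio of 0.985, with Hbb-b1 at 24.4 and 50.9 in the knockout libraries and 35.6 and 40.8 in the controls, so these rows did not rise in both knockout libraries and single libraries decide their direction (log2 fold change of Hbb-b1 0.41 without knockout replicate 1 and -0.62 without knockout replicate 2). A loss of germ cells in the knockout testis may raise these markers, and so may a response of the somatic cells themselves, which was not tested.

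The third pattern is that knockout replicate 2 lay farther from the controls than knockout replicate 1. Its lower depth does not account for this, since 90.6% of 1383 genes at least 2-fold from the controls in replicate 1 were farther in the same direction in replicate 2. More somatic cells with the same germ cells would lower both germ-cell lists alike. The pachytene list was lower in replicate 2 (median log2 RPKM ratio -0.48, 17 of 19 genes), while the autosomal meiotic entry list was not (0.04, permutation p over genes = 0.0022, two-sided). That p compares 1 library with 1 and treats genes as independent, so it does not measure variation between libraries. The somatic lists disagreed, with Sertoli and peritubular genes higher in replicate 2 (0.41 and 0.50) and Leydig and leukocyte genes little changed or lower (0.07 and -0.15). The haemoglobin rows were higher in replicate 2 by a median of 1.10, so the blood left in the 2 suspensions may differ. Apart from the share of somatic cells, no biological explanation of the difference between the 2 knockout libraries was tested.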
